A study of Mus musculus with 4 samples.

How the data were processed

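Gene expression was measured in induced hepatocyte-like (iHep) cells of C57BL/6 mice, which per the labels were derived from cells named MDFs. The cells were grown in 2D or 3D culture. Per the design text, the cells came from 2 independent experiments, iHep-1 and iHep-2, and each experiment gave 1 array per culture, so there were 2 arrays per group and 4 arrays in all, a number that limits the precision. Replicate 1 of each group is iHep-1 and replicate 2 is iHep-2. The titles of both 2D arrays carry a plus sign after the experiment's name and those of the 3D arrays do not. Its meaning is not given in the sources used here, so whatever it marks cannot be separated from culture.

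Total RNA was isolated with an RNeasy Micro kit and amplified and labelled with Cy3 using a Quick Amp kit, per the labels' protocols. Each sample was hybridised to its own 1-colour array of Agilent design 014868. Per the file headers, the 4 arrays lay on 1 slide and were scanned at 1 time, so slide and scan could not differ between groups. The deposited scanner files hold linear spot intensity values from Agilent Feature Extraction, including a background-corrected processed signal, mean and background signals, and per-spot flags. Its version is 9.5.1.1 per the submitters' processing notes and 10.7.1.1 per the file headers, and the sources used here do not settle which applies. Per the file headers, probe positions refer to mouse genome build mm9.

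The authors' series table also holds linear intensity values. Their sorted values differed by at most 0.000339 log2 units between the 2 arrays of iHep-1 and by at most 0.000409 between those of iHep-2, against 0.234 between experiments. They ranked probes almost as the processed signal did, with Spearman correlations across probes of 0.999996 to 0.999997. The deposited intensity columns had medians of 26.3 for both arrays of iHep-1 and 22.6 for both arrays of iHep-2. These values thus had equal distributions within each experiment but not across experiments, and their direction and linear scale followed from this comparison. They were used as an alternative.

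For the main values, log2 of the processed signal was taken and each array's 75th percentile over noncontrol spots was subtracted. Spots marked as nonuniform or as population outliers were left out (72 to 85 noncontrol spots per array), and spots of the same probe were averaged. No spot was saturated. Of 41174 probes, 24844 were named through an accession in a RefSeq gene table, 7855 through a current or unique older symbol, and 8475 kept the name in the files. The table belongs to another genome build, GRCm38.p6, and none of its coordinates was used. Probes were kept when well above background on at least 2 of 4 arrays with values on all 4. Each gene was represented by its probe with the highest mean, which gave 16450 tested genes. Of these genes, 5757 had several such probes, and in 45 a further probe differed by at least 1 log2 unit in the opposite direction.

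Groups were compared two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, and its prior had 1.58. Replicate numbers mark a shared experiment per the design text, and they therefore pair the arrays. The deviations of same-numbered arrays from their group means correlated across genes (r = 0.66). The fit with the experiment as a block is an alternative. For 33 fixed gene lists, camera was run with a preset correlation of 0.01, adjusted over the lists, and with estimated correlation and fry as alternatives. Genes differing by at least 1 log2 unit in the same direction in both experiments were also counted, without a test.

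The rule for named genes, the gene lists and the tests above were fixed before the data were examined. The rule takes the 10 largest log2 fold changes per direction among genes past the adjusted threshold. Where fewer pass, it fills up to 10 with symbols whose smaller difference over the 2 experiments was largest. It adds up to 4 members with the smallest p in each described list, and 20 fixed genes. Some genes that the rule takes are not reported. Genes named outside the rule are marked as chosen after their values were seen. Where no array of a group had a gene well above background, the fold is a bound. The bright group's mean was set against the dim group's mean of the higher of the probe's own value and the array's lowest signal well above background, on the normalized log2 scale.

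The limma step was tested on simulated data for the comparison of 3D with 2D, with 16450 genes at the real spread and 200 of them changed. It recovered 0 of 100 genes changed by 2 log2 units and 65 of 100 changed by 6 log2 units, with 3 false calls. At 0.1 times that spread it recovered 96 and 100 of 100, with 14 false calls. In simulated lists of independent genes, camera with the preset correlation called 17 of 17 lists shifted by 1 log2 unit and 0 of 16 unshifted lists. With an estimated correlation it called 0 of the 17. In the real lists the estimated correlation was 0.64 for cell cycle, 0.70 for cholesterol and 0.07 for cytochrome P450 genes. The simulation therefore does not show how often the preset correlation calls unshifted lists of correlated genes. Alternatives covered normalization, background correction, the filter on dim probes, marked spots, the probe rule, the authors' series table, the prior, the block and each left-out array. Spike-in scaling, the block combined with an intensity trend and robust prior or with an estimated correlation, and a filter on the brighter group were added after the data were seen. Spike-in controls were left out of the main comparison.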

Results

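Expression of 16450 genes was measured in iHep cells, hepatocyte-like cells induced from another cell type, in 2D and 3D culture, with 2 arrays per group. The experiments iHep-1 and iHep-2 each supplied 1 array of each culture. Signals well above background were found for 23746 probes in 2D and 24412 in 3D of iHep-1, and for 24378 in 2D and 23061 in 3D of iHep-2. The 75th percentile of the processed signal was 523, 594, 616 and 399 intensity units on these arrays in the same order. The comparison asks how gene expression differed between 3D and 2D cultures. Only the titles of the 2D arrays carry a plus sign, and what it marks is not given and would coincide with culture. Differences below are 3D minus 2D in log2 units after scaling each array to its 75th percentile, given for iHep-1 first and iHep-2 second, and higher or lower means relative to the other genes of an array. Scaling to spike-in controls instead moved the median of all genes to -1.08.

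In 3D culture, genes of drug metabolism, plasma protein secretion and amino acid breakdown were higher, and genes of the cell cycle were lower, as gene lists by camera with a preset correlation. Each of these lists had an adjusted p of 0.516 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at least 194-fold brighter in 3D by its brighter probe. The other Cyp7a1 probe gave a mean difference of 6.99. Arg1, the arginase of the urea cycle, differed by 5.91 and 9.20. Urea cycle and amino acid genes had a list median of 1.04, which was -0.053 with spike-in scaling. Mki67, a marker of cycling cells, differed by -2.02 and -5.26. Alb, the main plasma protein of hepatocytes, was already bright in 2D (8.96 ± 0.21 log2 units above the 75th percentile, SD, n = 2) and stood at 9.26 ± 0.44 in 3D. No single gene passed the adjusted threshold, so these gene values are descriptions of 2 experiments.

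By limma, 0 genes were higher and 0 lower in 3D, with a smallest adjusted p of 0.496. At an unadjusted p under 0.05 there were 1157 genes, 667 higher and 490 lower, where 822 would be expected by chance. With the experiment as a block, limma again called 0 genes, with a smallest adjusted p of 0.125 and 2178 genes at an unadjusted p under 0.05. The block combined with an intensity trend and robust prior, chosen after the data were seen, called 19 genes higher and 0 lower.

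By size alone, 700 genes were at least 2-fold higher in 3D in both experiments and 350 were at least 2-fold lower. These counts depend on the processing: they were 331 and 130 with normexp background correction, 457 and 204 over probes well above background on all 4 arrays, and 168 and 3298 with spike-in scaling, chosen after the data were seen. Independent lists would share 162.1 and 55.7 genes. A further 132 genes differed at least 2-fold in opposite directions. When the arrays were paired by culture instead, 842 genes were at least 2-fold higher and 945 lower in iHep-2 than in iHep-1 in both cultures. The crossed pairing gave 645 and 763. With the main scaling and filter, differences between the experiments (1787 genes) thus outnumbered those between cultures (1050 genes). Across genes, the differences of the 2 experiments correlated with r = 0.54 and rho = 0.45, and genes are not independent replicates. Arrays of one experiment were closer (r = 0.970 and 0.939) than arrays of one culture (0.933 and 0.933).

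**Figure D1:**
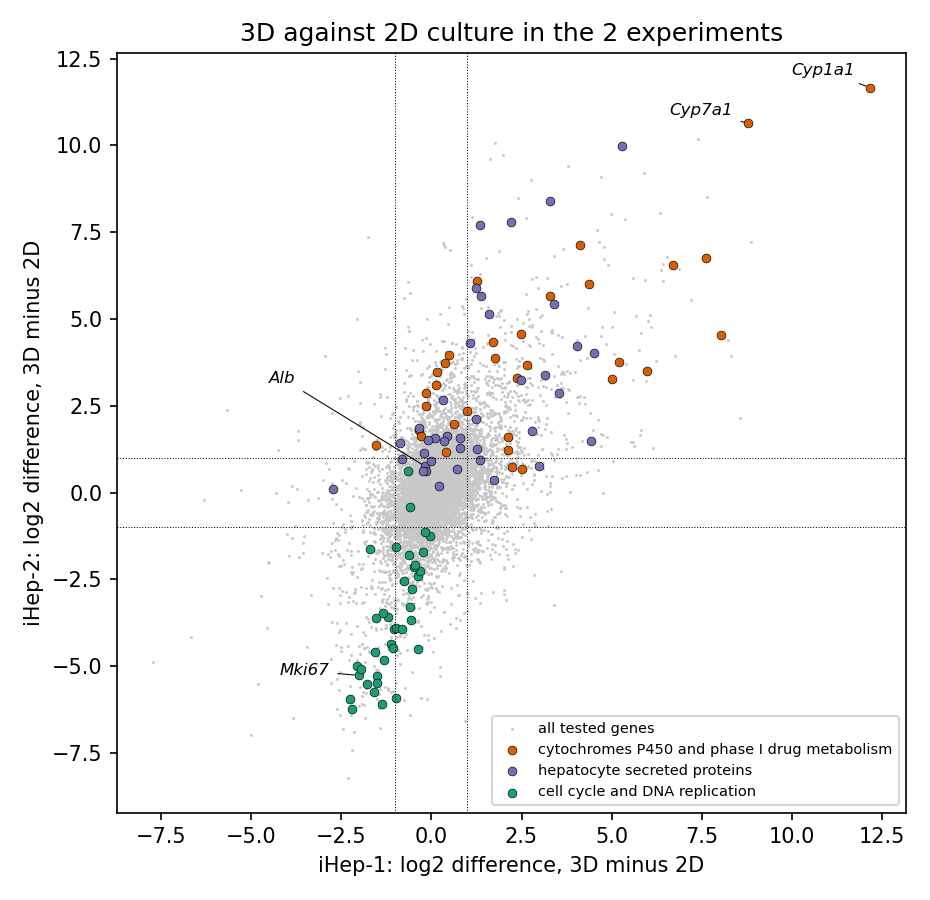
Each point is a tested gene, with its log2 difference 3D minus 2D in iHep-1 on the x axis and in iHep-2 on the y axis; dotted lines mark 2-fold differences and colours mark 3 gene lists. Cyp1a1 and Cyp7a1 lie far to the upper right at places that rest on 2D values not well above background. By the probes plotted they were at least 985-fold and 194-fold brighter in 3D. Mki67 (-2.02 and -5.26) lies at the lower left.

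The 10 symbols with the largest shared positive difference included enzymes of drug and amino acid metabolism. Cyp1a1, which oxidises aromatic hydrocarbons, was not well above background in 2D and was at least 985-fold brighter in 3D (adjusted p = 0.496, limma). Its probe lies on chromosome 9 at 57551535 to 57551594 of mm9. Cyp7a1 (chromosome 4, 6193456 to 6193515) was likewise at least 194-fold brighter (adjusted p = 0.649, limma), while its other probe gave a mean difference of 6.99. Sds, the serine dehydratase (chromosome 5, 120933105 to 120933164), was at least 78.1-fold brighter (adjusted p = 0.496, limma). Saa2, an acute phase protein, differed by 7.38 and 10.19, and Cyp2c55 by 8.86 and 7.23. Aadac differed by 7.62 and 6.75, and Cyp2b10 by 6.69 and 6.57. Ugt2b5, a glucuronosyltransferase, differed by 6.87 and 6.44, Ugt2b37 by 6.42 and 6.59, and Cyp2b13 by 6.38 and 6.41. A second Cyp2b13 probe gave a mean difference of 1.01, and probes of such close relatives can cross-hybridise. The last 7 of these 10 genes, from Saa2 on, were well above background on 3 of 4 arrays, so 1 of their 2 differences rests on a dim value.

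The 10 symbols with the largest shared negative difference came from varied groups. Col14a1, a fibril-associated collagen, differed by -4.99 and -6.98 (probe on chromosome 15, 55352132 to 55352191). Clca1 differed by -7.72 and -4.88, Kcne2, a potassium channel subunit, by -6.66 and -4.16, and Fbxw18 by -4.54 and -3.89. Pimreg was not well above background in 3D and at least 29.95-fold brighter in 2D, Tnc, the matrix protein tenascin C, at least 4.25-fold, and Fbxw14 at least 3.31-fold. Socs2, an inhibitor of cytokine signalling, differed by -2.99 and -5.10, Popdc2 by -3.33 and -2.96, and Slc7a3, a cationic amino acid transporter, by -2.86 and -3.22. Col14a1 and Fbxw18 were well above background on 3 of 4 arrays, so their iHep-2 differences rest on a dim 3D value. The adjusted p of these 10 genes lay between 0.684 and 0.706 (limma).

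Genes of oxidative drug metabolism were higher in 3D as a list. Among 33 tested cytochromes P450 and phase I genes, 28 were higher in both experiments, 0 lower in both, and 19 at least 2-fold higher in both (list medians 2.13 and 3.51). Cyp3a25 differed by 4.13 and 7.15, and Cyp1a2 was at least 33.2-fold brighter in 3D. Camera gave an adjusted p of 7.62e-13 for the list, and an adjusted p of 0.516 with an estimated correlation. No member passed over all genes and 6 passed adjusted over the list alone, or 19 with the experiment as a block. The median was 2.81 for the mean of both, and 1.72 with spike-in scaling.

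Phase II conjugation and hepatic transporter genes were also higher in 3D, with 26 of 31 higher in both experiments and 15 at least 2-fold higher in both. Abcc2, the canalicular export pump for conjugates, differed by 3.65 and 3.48, and Abcb11, the bile salt export pump, by 2.80 and 6.14. Ugt1a1, which conjugates bilirubin, was at least 6.66-fold brighter in 3D, and the transporter Slco1a4 at least 3.67-fold. Camera gave an adjusted p of 9.36e-09, and an adjusted p of 0.516 with an estimated correlation. No member passed over all genes and 0 adjusted over the list alone, or 11 with the experiment as a block. The median was 1.31 for the mean of both, and 0.22 with spike-in scaling.

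Plasma protein genes were higher in 3D as a list, although Alb differed by only -0.17 and 0.76. The 75th percentiles used for scaling differed by 0.18 and -0.63 between the cultures. A probe of equal unscaled signal in both cultures would thus differ by about as much with the opposite sign. The Alb differences therefore show little beyond this scaling. Of 39 tested hepatocyte secreted proteins, 29 were higher in both experiments and 18 at least 2-fold higher in both (medians 1.24 and 1.57, 1.26 for the mean of both, and 0.16 with spike-in scaling). The apolipoproteins Apoc3 (3.39 and 5.42) and Apoa2 (3.29 and 8.41), the haem-binding protein Hpx (1.24 and 2.12) and the anticoagulant zymogen Proc (4.03 and 4.22) had the smallest p. Ttr, the thyroid hormone carrier transthyretin, differed by -0.33 and 1.86. Camera gave an adjusted p of 3.56e-09, and an adjusted p of 0.516 with an estimated correlation. Adjusted over the list alone, 0 members passed, as over all genes, or 10 with the experiment as a block, and the median was 0.75 without 3D replicate 2.

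Urea cycle and amino acid genes were higher in 3D relative to other genes, with a median of 1.04 that was -0.053 with spike-in scaling. Of 29 tested, 21 were higher in both experiments, 2 lower in both and 12 at least 2-fold higher in both. Hal, which deaminates histidine, differed by 4.27 and 4.51, and Cps1, the first enzyme of the urea cycle, by 2.59 and 2.33. Hpd, of tyrosine breakdown, was at least 13.4-fold brighter in 3D. Camera gave an adjusted p of 1.40e-07, and an adjusted p of 0.516 with an estimated correlation. No member passed over all genes and 6 passed adjusted over the list alone, or 11 with the experiment as a block. The median was 1.61 without 2D replicate 1 and 1.88 without 3D replicate 1.

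Glucose and glycogen genes of liver were higher in 3D as a list, with 13 of 16 higher in both experiments and medians of 0.99 and 3.19 (2.11 for the mean of both, and 1.01 with spike-in scaling). Glyctk differed by 1.13 and 3.81 and Ppp1r3c, a glycogen-targeting phosphatase subunit, by 1.16 and 1.29. The camera adjusted p was 0.000549, and the adjusted p was 0.516 with an estimated correlation. In fatty acid oxidation and lipid handling, 24 of 29 genes were higher in both experiments, at smaller medians of 0.28 and 0.996 (0.74 for the mean of both, and -0.36 with spike-in scaling). Ehhadh, of peroxisomal oxidation, differed by 1.65 and 2.03, Scd1, a fatty acid desaturase, by 1.87 and 3.28, Cpt2 by 0.90 and 1.52, and Fabp1 by 1.19 and 3.29. The camera adjusted p was 3.54e-07, and the adjusted p was 0.516 with an estimated correlation. In each of these 2 lists 0 members passed over all genes and 0 adjusted over the list alone, or 1 glucose and 0 fatty acid genes with the experiment as a block. The glucose median was 3.62 without 3D replicate 1 and 0.98 without 3D replicate 2, and the fatty acid median 0.38 without 2D replicate 2.

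Cholesterol genes had list medians of opposite sign in the 2 experiments, a difference that was not tested with 1 array per culture in each. Of 24 tested genes of cholesterol biosynthesis and uptake, 23 were higher in 3D in iHep-2 and 8 in iHep-1, with medians of 1.32 and -0.25. Hmgcs1 differed by 0.26 and 1.92, Pmvk by 0.70 and 1.99, and Ebp by 0.57 and 0.76. The list was called higher relative to other genes by camera (median 0.54, or -0.55 with spike-in scaling; adjusted p = 0.0079), and the adjusted p was 0.662 with an estimated correlation. Its adjusted p was 0.625, with a median of -0.18, without 2D replicate 2, and 0.0686 without 3D replicate 2. Over the alternatives with the preset correlation it ran from 1.79e-09, with a median of 1.27, without 2D replicate 1 to 0.625. No member passed over all genes and 0 adjusted over the list alone.

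Cell cycle genes were lower in 3D, and by more in iHep-2. Over all genes, the differences also had a wider SD in iHep-2 (1.20) than in iHep-1 (0.83). Of 38 tested cell cycle and DNA replication genes, 37 were lower in both experiments and 19 at least 2-fold lower in both, with medians of -1.01 and -3.79 (-2.42 for the mean of both, and -3.51 with spike-in scaling). The mitotic kinase Aurkb differed by -2.27 and -5.94, the latter resting on a dim 3D value, and the thymidylate synthase Tyms by -0.97 and -1.56. Ttk, a kinase of the spindle checkpoint, was not well above background in 3D and was at least 3.84-fold brighter in 2D. Camera gave an adjusted p of 8.58e-18, and an adjusted p of 0.516 with an estimated correlation. No member passed over all genes and 0 adjusted over the list alone. The median was -1.58 without 2D replicate 2. Whether the size differed between the experiments was not tested, since each had 1 array per culture. Cdkn1a, which inhibits cyclin-dependent kinases, differed by 1.38 and 1.39, whereas the list of 7 such inhibitors was not called by camera (adjusted p = 0.632; 1 member passed adjusted over the list alone).

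Hippo pathway components and targets of YAP and TEAD, the transcriptional regulators that the pathway restrains, were lower in 3D as lists. Of 20 tested components, 16 were lower in both experiments, with medians of -0.34 and -0.73 (-0.58 for the mean of both, and -1.68 with spike-in scaling). Tead4 differed by -1.18 and -2.45, and Wwtr1, which encodes the YAP-related coactivator TAZ, by -0.53 and -1.34, while Yap1 differed by -0.32 and 0.26. Wwc1 differed by -0.62 and -0.78 and Mob1a by -0.39 and -0.72; both encode proteins that promote pathway signalling, so the list mixes regulators of opposite effect. The camera adjusted p was 0.000246, and the adjusted p was 0.516 with an estimated correlation. The median was -0.33 without 2D replicate 2 and -0.28 without 3D replicate 2.

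In the YAP/TEAD target signature, 14 of 22 genes were lower in both experiments, 2 higher in both, and 7 at least 2-fold lower in both (median -1.02, and -2.12 with spike-in scaling). The matricellular genes Ccn2 and Ccn1 differed by -1.80 and -2.92 and by -0.71 and -4.08. Amotl2 differed by -1.64 and -2.73, Tgfb2 by -2.06 and -3.85 (the latter from a dim 3D value), Gadd45a by -1.01 and -3.24, and Ptpn14 by -0.53 and -1.58, while another Ptpn14 probe gave a mean difference of 0.20. Ankrd1 differed by -5.94 in iHep-2, and in iHep-1 it was at the same dim level in both cultures (-0.13). The camera adjusted p was 0.000661 for the signature, and the adjusted p was 0.638 with an estimated correlation. It was 0.0575, with a median of -0.37, without 2D replicate 2, and ran down to 2.04e-08 over the alternatives with the preset correlation; the median was -0.52 without 3D replicate 2. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

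**Figure D2:**
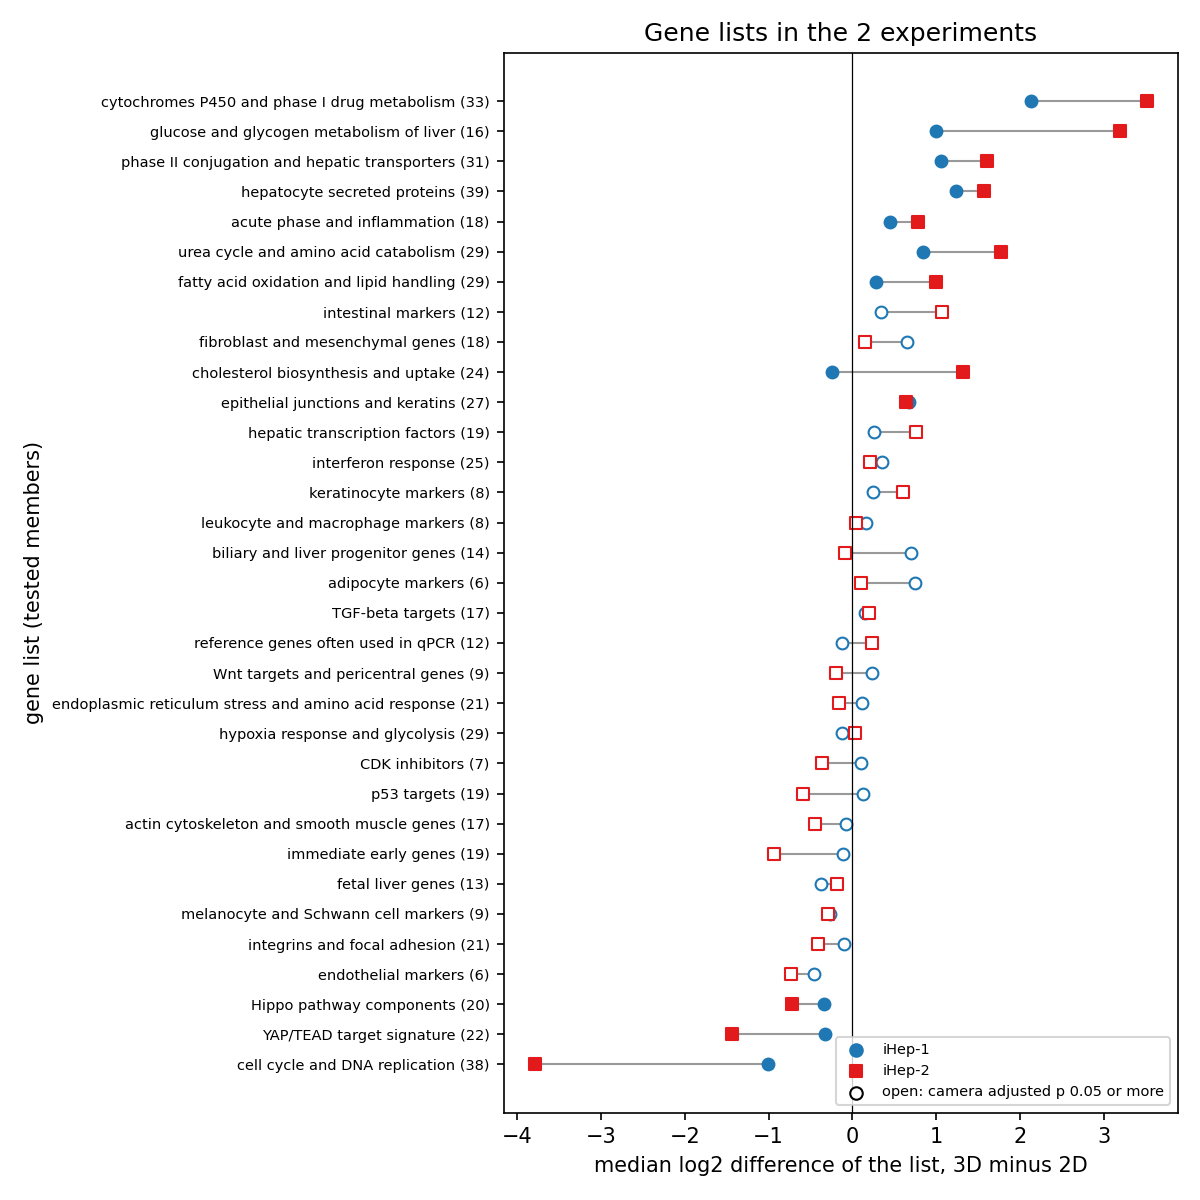
Each row is a gene list with its number of tested members; the x axis is the median log2 difference 3D minus 2D, circles are iHep-1, squares are iHep-2, and open symbols mark lists with a camera adjusted p of 0.05 or more. The P450 list (2.13 and 3.51) lies at the top and the cell cycle list (-1.01 and -3.79) at the bottom.

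Epithelial and acute phase genes were called higher in 3D relative to other genes. For the mean of both experiments, the epithelial median was 0.54 and the acute phase median 1.15, or -0.56 and 0.052 with spike-in scaling. In iHep-1 and iHep-2 the medians were 0.67 and 0.64 for epithelial genes and 0.45 and 0.79 for acute phase genes. Of 27 epithelial junction and keratin genes, 13 were higher and 4 lower in both experiments. Gjb1, a gap junction protein of hepatocytes, differed by 2.62 and 2.64, Marveld3 by 2.73 and 2.15, and Tjp3 by 1.36 and 2.42. Grhl2, a regulator of epithelial genes, was at least 3.52-fold brighter in 3D. The camera adjusted p was 0.0227, the adjusted p was 0.516 with an estimated correlation, and it was 0.297, with a median of 0.29, without 2D replicate 1. Over the alternatives with the preset correlation it ran from 0.00045 to 0.297, and the median was 0.82 without 3D replicate 1. Cdh1, the epithelial cadherin, differed by 0.66 and -0.51. Of 18 acute phase and inflammation genes, 9 were higher and 6 lower in both experiments. Besides Saa2, the smallest p were those of the plasma proteins Orm1, at least 12.6-fold brighter in 3D, and Orm2 (5.38, from a dim 2D value, and 3.70), and of the chemokine Ccl7 (1.35 and 2.09). The camera adjusted p was 0.0243, the adjusted p was 0.516 with an estimated correlation, and it was 0.209 without 3D replicate 1. It ran from 2.20e-08 to 0.649, the latter over probes well above background on all 4 arrays, where the median was 0.28. The median was 0.53 without 2D replicate 1. Adjusted over the list alone, 0 epithelial and 3 acute phase genes passed, against 0 over all genes, or 2 and 7 with the experiment as a block.

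Hepatic transcription factors were not called as a list (adjusted p = 0.121 by camera), but were with the experiment as a block (adjusted p = 0.0346; adjusted p = 0.797 with an estimated correlation). Over the alternatives with the preset correlation the adjusted p ran from 0.0253 to 0.275. The 0.0253 came from spike-in scaling, where the list median was -0.62 against -1.08 for all genes. It thus still lay above the other genes, as did the median of 0.47 in the main fit. Creb3l3, a liver regulator of lipid genes, differed by 2.66 and 5.13, and Nr1i3, the receptor CAR, by 1.59 and 3.51. Nr1h3 differed by 0.65 and 1.47 and Ppara by 0.74 and 1.32. Hnf4a differed by -0.81 and 0.23, with a mean difference of up to 2.15 for another of its probes. Foxa3 differed by 0.77 and 0.60, Foxa2 by 2.83 and -2.38 on dim signals, and Cebpa by 0.17 and 1.55. Foxa1 was not well above background on any array.

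Fetal, biliary and fibroblast genes were not called as lists (adjusted p = 0.253, 0.533 and 0.632 by camera). Without 3D replicate 2, fetal genes were called lower (adjusted p = 0.0277) and fibroblast genes higher (adjusted p = 0.0350) by camera, and without 2D replicate 2 biliary genes were called higher (adjusted p = 0.00292). Afp, the fetal plasma protein alpha-fetoprotein, differed by -6.29 and -0.22, so its mean of 4.46 ± 5.03 (SD, n = 2) in 3D describes neither array. Krt19 and Sox9, markers of bile duct cells, differed by 1.504 and -0.18 and by 0.21 and 0.25. Of 18 tested fibroblast and mesenchymal genes, 9 were higher and 5 lower in both experiments. S100a4 differed by 3.74 and 2.61, Snai2, a mesenchymal transcription factor, by -1.46 and -1.65, and Pdgfra by 0.65 and 0.65. Acta2, of smooth muscle actin, differed by -0.12 and -0.31, while another Acta2 probe gave a mean difference of -1.35. Col1a1 was well above background on 1 array.

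**Figure D3:**
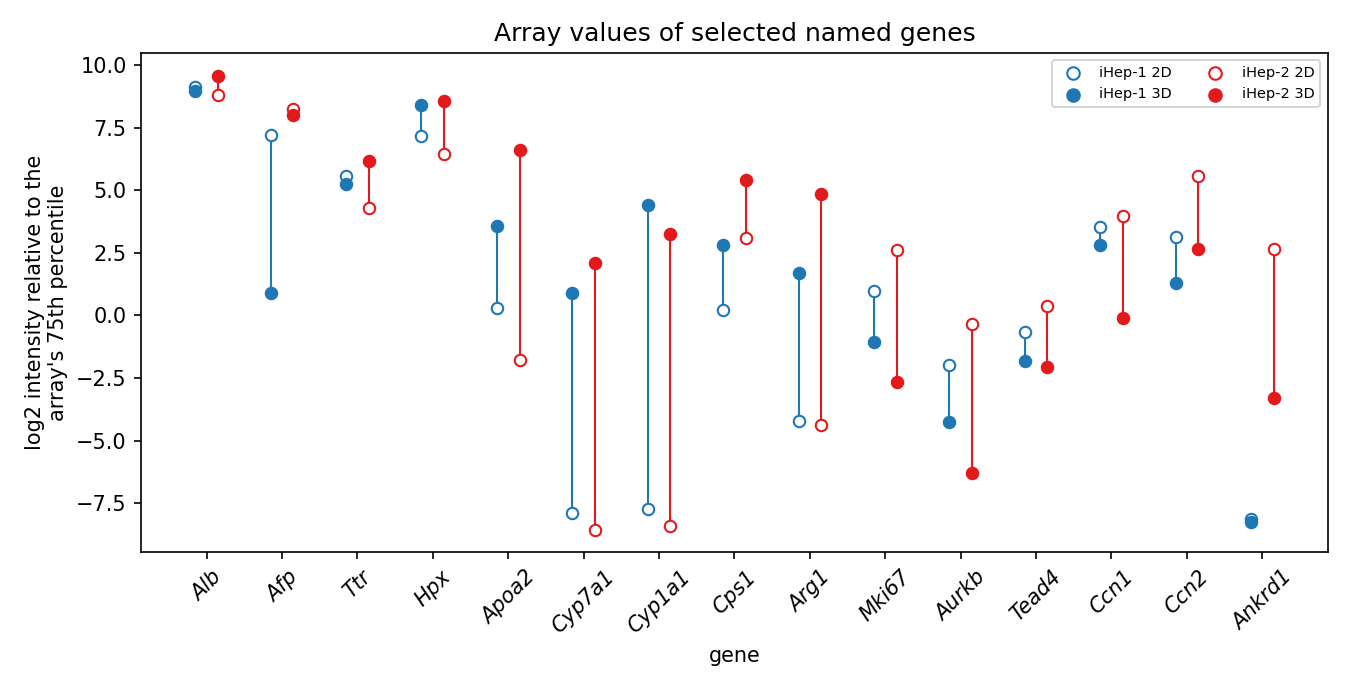
Open circles are 2D and filled circles 3D arrays, blue for iHep-1 and red for iHep-2, on a log2 axis relative to each array's 75th percentile. Alb is bright on each array (means 8.96 in 2D and 9.26 in 3D), while the Afp difference is -6.29 in iHep-1 and -0.22 in iHep-2.

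Lists for other cell types gave camera adjusted p of 0.0525 for intestinal, 0.121 for keratinocyte, 0.267 for endothelial, 0.356 for melanocyte and Schwann cell, 0.379 for adipocyte and 0.461 for leukocyte and macrophage markers. The intestinal list, whose Apoa4 (1.91 and 4.78) and Fabp2 (4.12 and 2.77) encode lipid-handling proteins, was called higher by camera with the block (adjusted p = 0.0164). With the block and an estimated correlation its adjusted p was 0.797. Over the alternatives with the preset correlation its adjusted p ran from 0.00187 to 0.365. The 0.00187 came from spike-in scaling, where its median was -0.43 against -1.08 for all genes. Its median was 1.19 without 3D replicate 1 and 0.98 without 2D replicate 2. Remaining lists were not called either. Their adjusted p was 0.0595 for immediate early genes, 0.147 for integrins and focal adhesion and for the interferon response, 0.251 for p53 targets, and 0.253 for actin cytoskeleton genes. It was 0.327 for hypoxia and glycolysis, 0.379 for Wnt targets and pericentral genes, 0.407 for endoplasmic reticulum stress, 0.631 for qPCR reference genes and 0.632 for TGF-beta targets. For immediate early genes it ran from 0.00434 to 0.635 over the alternatives with the preset correlation, and the list was called lower with normexp (0.0152), with no filter on dim probes (0.00516), over probes well above background on all 4 arrays (0.0152), without 2D replicate 1 (0.00434) and without 3D replicate 1 (0.0269). Without 2D replicate 1, camera also called actin (adjusted p = 0.0228) and p53 genes (adjusted p = 0.0343) lower, and without 3D replicate 2 interferon genes (adjusted p = 0.0144) higher. Of the 33 lists, 9 were thus higher and 3 lower in 3D by camera, and 0 by an estimated correlation or by fry. The TGF-beta list is an example of split members, with Loxl2 at -1.93 and -2.16 and Tgfbi at 0.36 and 2.79. The CDK inhibitor list had a median of -0.16 and a mean of 0.12, and camera's direction was that of the mean. The Wnt list had medians of 0.23 and -0.19. In the lists not called, 0 members passed adjusted over the list alone, except 1 each of the CDK inhibitor and Wnt lists. With the experiment as a block, 4 endothelial, 3 Wnt, 2 fibroblast, 2 intestinal, 1 TGF-beta and 1 CDK inhibitor genes passed.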

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

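The tests in this part were chosen after the results were seen. E1A spike-in controls, which are outside the comparison of cultures, stood apart on 1 array: on the 3D array of iHep-1 the 6 spike-ins well above background on all 4 arrays were on average 1.85 log2 units brighter than on the 2D array, which was 1.67 beyond the difference of the gene probes' 75th percentiles (0.18); in iHep-2 the spike-in difference was -0.11. More spike-in per sample RNA in that reaction would move all spike-ins alike; their differences ran from 1.26 to 2.27 with an SD of 0.415, against 0.109 in iHep-2, so this stays open. No biological explanation was tested.

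Cell cycle genes had medians of -1.01 and -3.79. Unequal scaling of the arrays would place them within random lists of equal brightness, but in 10000 such lists the lowest median lay at least 0.672 above that of the cell cycle list in both experiments. Loss of cells that supply most fibroblast transcripts is argued against for the 18 tested genes of the 30 in that list. These had medians of 0.65 and 0.15, and their lower quartile lay at least 0.892 above the cell cycle median in each experiment. Of the 18, 0 were as low in both, 2 were at least 2-fold lower in both and 1 at least 2-fold higher. Outside the list, the matrix genes Col14a1 (-4.99 and -6.98) and Tnc (at least 4.25-fold brighter in 2D) were lower. The argument thus covers only the tested fibroblast genes of the list. Loss and no loss of a small cycling share of fibroblast-like cells cannot be told apart, because other cells that express such genes could hide it; 27.8% of the 18 genes were lower in both experiments and 9 were higher in both. An effect of 3D culture on proliferation stays open as a hypothesis.

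Cholesterol genes were higher in 3D in iHep-2, with a median of 1.32, and not in iHep-1, with -0.25. Too high a scaling of the 3D array of iHep-2 was argued against, since the iHep-2 median lay 0.65 above the highest of 10000 random lists of equal brightness. A larger response of all liver genes in iHep-2 stays open: the list's median difference between experiments (1.51) lay at the 93.8th percentile of 10000 draws from 196 genes of the 7 other liver lists, between 0.52 for phase II and 2.82 for glucose genes. A difference between the 2 experiments may account for it, and stays untested with 1 array per culture and experiment.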

How the results depend on the processing

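Spike-in scaling, the 2 combined fits with the block and the filter on the brighter group were chosen after the data were seen. Counts of genes past the adjusted threshold were 0 in both directions under each alternative chosen before, the replicate block, thresholds and left-out arrays included. The block with an intensity trend and robust prior gave 19 higher. Spike-in scaling gave 76 higher and 213 lower; it moved the median of all genes to -1.69 in iHep-1 and -0.48 in iHep-2, an offset shared by all genes that enters every residual, so these calls are not comparable. Genes at least 2-fold higher and lower in both experiments numbered 331 and 130 with normexp, 457 and 204 over probes above background on all 4 arrays (fewer genes tested, 14585), and 168 and 3298 with spike-in scaling. The correlation between experiments was 0.37 with no filter on dim probes, which moves the median of all genes to 0.20. Lists lower in 3D numbered 10 with no filter, 5 with spike-in scaling, and 2 to 6 without one array (6 without 2D replicate 1); lists higher in 3D numbered 8 to 10 without one array. With an estimated correlation, with fry, and with the replicate block and an estimated correlation, 0 lists were higher and 0 lower. In simulation the estimated correlation also called no shifted list, so its misses do not separate absent from undetected shifts. The replicate block gave 11 lists higher and 3 lower, including the 12 of the main test. The cholesterol median ran from -0.18 without 2D replicate 2 to 1.27 without 2D replicate 1. With spike-in scaling the median took the other sign in 15 of 33 lists, against -1.08 for all genes. These included cholesterol (-0.55), urea cycle and amino acid (-0.053), fatty acid (-0.36), epithelial (-0.56), hepatic transcription factor (-0.62), Wnt (-1.08) and intestinal genes (-0.43). Of 21 lists not called, 14 were called under some alternative with the preset correlation. The cause was not tested except where stated. Of 160 named genes, 45 took the other sign in some alternative, among them Afp without 3D replicate 1 and Ankrd1 without 2D replicate 2. Leaving out an array leaves a group with 1 array, assumed to vary like the other group. Dim signals limit folds of genes near background in one culture.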

Other observations

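The tests and genes in this part were chosen after their values were seen. The experiments differed in gene level in both cultures. With culture and experiment in one limma fit, 303 genes differed between iHep-2 and iHep-1 at an adjusted p under 0.05 (differences given next are iHep-2 minus iHep-1, in 2D and 3D). Agtr1a, an angiotensin receptor, and Slco2b1 were not well above background in iHep-2 and were at least 342-fold and 321-fold brighter in iHep-1. Tinag was not well above background in iHep-1 and was at least 233-fold brighter in iHep-2. Foxa3 differed by 3.80 and 3.62 log2 units (adjusted p = 0.0403, limma). Biliary and progenitor genes (median 1.28, adjusted p = 0.0448) and secreted protein genes (median 0.40, adjusted p = 0.0450) were higher in iHep-2 by camera and fibroblast genes lower (median -0.60, adjusted p = 0.0448), each with an adjusted p of 0.962 with an estimated correlation. The difference 3D minus 2D had opposite signs in iHep-1 and iHep-2 for some genes: Rcan2 by 3.39 and -3.24 (each from a dim value), Muc5ac by -2.96 and 3.92, and Gpc3, a fetal liver proteoglycan, by -2.76 and 2.30.

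Several antioxidant genes had higher values in 3D. Nqo1 differed by 2.75 and 2.54, Srxn1 by 1.45 and 1.60 and Gclm by 0.92 and 1.61. A hypothesis is that targets of the transcription factor NRF2 move together. Of 10 targets not looked at when the list was written, 80% were higher in both experiments, among them Cbr3 (3.66 and 3.01). Camera gave these 10 targets a p of 0.000415, or 0.000727 adjusted over the 7 added lists. Some of these lists hold genes seen before and overlap the unseen ones, so the adjustment leans on values already seen. With an estimated correlation, the adjusted p of the 10 targets was 0.262. Camera set these targets against all other genes, and their median of 0.77 lay below that of the phase II and transporter list (1.31). A shared regulator is therefore not separated from the higher values of drug metabolism genes, and stays a hypothesis. The NRF2 gene itself, Nfe2l2, differed by 0.24 and -0.09, and the protein was not analysed here.

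The stress genes Ddit3 (-1.88 and -3.16), Trib3 (-2.13 and -2.87) and Chac1 (-3.56 and -1.44) had lower values in 3D. Of 18 endoplasmic reticulum chaperones, 11.1% were lower in both experiments and 14 were higher in both. Only 6 of these 18 had not been looked at before. Of those 6, 5 were higher and 1 was lower in both experiments, and camera did not call them as a list. For the chaperones, these values argue against a lower unfolded protein response as a whole, but most of them had already been seen. For ATF4 and CHOP targets, 71.4% of 7 not looked at before were lower in both experiments, including Phgdh (-2.57 and -1.21), under the 75% set as the requirement. Camera gave these 7 a p of 0.0114 (lower), or 0.0133 with the same adjustment over the added lists. With an estimated correlation their adjusted p was 0.262, so a shift of this group stays open. Of 7 tested aryl hydrocarbon receptor targets, 4 had higher values in both experiments, namely Cyp1a1, Cyp1a2, Nqo1 and Ugt1a6b (5.59 and 6.18). All 7 were higher in iHep-1 and 3 were lower in iHep-2, among them Tiparp (0.09 and -0.41) and Cyp1b1 (2.51 and -1.29). Camera gave the list an adjusted p of 4.88e-05 (higher), and 0.262 with an estimated correlation, on values already seen.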
